A study of Homo sapiens with 3 samples.

How the data were processed

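CUT&RUN libraries were made from CT27 human trophoblast stem cells with antibodies against GATA2 (rabbit), GATA3 (mouse) or a rabbit IgG, per the labels. Each of the 3 samples is titled as pooled, and the labels name 1 sample per antibody. Per the labels' protocols, cutting was stopped in a buffer with RNase A, and both a ChIP and an RNA library kit are named. The files analysed were 2 lists of consensus intervals deposited by the authors, 1 for GATA2 and 1 for GATA3, assigned to antibody by name. The interval starts and ends are coordinates in bp on hg38, per the submitters' processing notes, and the score deposited by the authors for each interval was 0 throughout, so peaks could not be ranked by strength. Which libraries entered the consensus, and by what rule, is not given in the sources used here. The submitters' processing notes name bcl2fastq, FastQC 0.11.9, Trim Galore 0.6.4, BWA 0.7.17-r1188, SAMtools 1.10, bedtools 2.29.2, deepTools 3.4.3, Picard 2.23.1, R 3.6.3, MACS2 2.2.7.1, featureCounts 2.0.1 and MultiQC 1.9, with no role or order. An IgG list was not analysed here, so no background measured the same way stands beside the counts. The depth of each sample is unknown.

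Peaks on chromosomes 1 to 22, X and Y were analysed, and coordinates are printed counting from 1. Genes came from the RefSeq table for GRCh38 patch 14, whose build matches hg38, and chromosome lengths from GenomeInfoDb 1.38.1. The table gives gene starts and ends but neither strand nor exons, and no genome sequence was used. Transcription starts could not be told from gene ends, so distances were taken to either end of a gene, exons and introns were not separated, and the planned motif tests were not run. For the same reason the planned test of gene lists, within 25 kb of a transcription start against all other genes, was replaced by one listed beforehand as another setting: a peak midpoint in the gene body or within 25 kb of it, against 10000 random sets of protein-coding genes drawn from the 200 genes nearest in length to each member. That choice was settled after counts at several distances had been seen. The nearest equivalent of the planned test, within 25 kb of either gene end by Fisher's exact test, is among the alternatives and called the same number of lists.

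Overlap meant at least 1 bp in common, and the count was checked with bedtools 2.31.1. Chance was taken from 1000 random placements of the GATA3 peaks, widths kept, leaving out stretches over 3 Mb with neither gene nor peak, 140 Mb in all. Annotation classes used the peak midpoint and the same kind of placements. Pseudogene counts used midpoints too. The difference between lists was tested with Fisher's exact test on genes with a peak of 1 list only. All tests were two-sided, with Benjamini-Hochberg adjustment over the 28 combinations of gene list and peak list, the 14 list differences or the 9 annotation tests, and a threshold of 0.05. The smallest p was 0.002 from placements and 0.0002 from gene sets. Wilson and exact Poisson intervals at 95% cover counting error only. Neighbouring genes can share a peak and are not independent, so the p-values describe these lists. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.

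The gene lists, the other settings to try and the rule for named genes were fixed before the data were examined. The rule took GATA2 and GATA3 with every peak within 100 kb, of each list up to 4 genes with peaks of both lists and up to 4 with peaks of 1 list, nearest peak first, the 10 genes with the most peaks within 100 kb per list, and the 3 widest shared, GATA2-only and GATA3-only peaks. Among the genes with the most peaks, those near one already taken were left out, and ties went to the nearest peak. Gene ends stood in for transcription starts in this rule too. The 3 Mb rule, placements within 1 Mb of each peak, the 500 kb limit, the 400 bp width class, the gene body and flank counts, and the pseudogene counts were chosen after seeing the data. Alternatives covered the definition of overlap, wider peaks only (at or above the median width), list size, contigs, distance to genes, gene matching and clustered genes. Matching on the number of neighbouring genes replaced the match on length. To count clustered genes once, only the longest of the list members within 100 kb of each other was kept, whatever its peaks.

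The procedures were tested on simulated data. With 300 planted overlaps between lists of the real sizes, 309 were found where chance gave 7.02. Planted peaks began where a GATA2 peak began, so this checked the count only. Of 20 random GATA3 lists set against the same random GATA2 list, 0 passed 0.05. They were drawn like the chance placements, so this does not give the false-call rate for real lists. Random peak lists gave 0 calls in 560 gene list tests over 20037 protein-coding genes. Their peaks were spread evenly within each chromosome, so they lacked the 1.54-fold excess of the real GATA3 list near gene ends. The 0 calls therefore do not give the false-call rate for a list with that excess. Peaks planted in 15% of syncytiotrophoblast genes were called in 15 of 20 simulations of the GATA3 list, and in 30% of them in 20 of 20.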

Results

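The data came from CUT&RUN, in which protein A/G-MNase cuts chromatin where an antibody is bound and the released DNA is sequenced, in CT27, an established line of human trophoblast stem cells. Trophoblast stem cells can form both the syncytiotrophoblast, the multinucleated hormone-secreting layer of the placenta, and extravillous trophoblast, which invades the uterus. The 3 samples were IgG, GATA2 and GATA3, with 1 pooled sample per antibody. GATA2 and GATA3 are zinc-finger transcription factors of the trophoblast. The GATA2 list held 8108 peaks, of which 8068 lay on chromosomes 1 to 22, X and Y, and the GATA3 list held 5457, of which 5431 did. Median peak width was 214 bp in both lists, with a 95% bootstrap interval of 213 to 215 bp for GATA2 and 212 to 217 bp for GATA3. An IgG list was not analysed here, the read depth is unknown, and no lists of separate replicates were analysed here. Intervals and tests therefore cover counting error over peaks or genes in these lists, and differences between the antibodies had no replicate check.

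The first comparison asked which sites were in both lists. The lists shared few sites, and the shared ones included the gene bodies of FTL, the ferritin light chain, STIM1, a calcium sensor of the endoplasmic reticulum, and LAMA5, a laminin chain. The FTL site lay at chromosome 19, 48965355 to 48965568 in the GATA2 list (hg38) and 48965323 to 48965566 in the GATA3 list. At STIM1 the GATA2 interval was chromosome 11, 3991951 to 3992139, and at LAMA5 it was chromosome 20, 62327630 to 62327873. These genes were chosen after their positions were seen. The widest shared GATA2 intervals were 327 bp on chromosome 1 (143192863 to 143193189), outside annotated genes, 322 bp in the noncoding gene MIR193BHG on chromosome 16 (14306321 to 14306642) and 281 bp in DUSP22, a phosphatase gene, on chromosome 6 (312524 to 312804). In all, 25 peaks of each list overlapped a peak of the other by at least 1 bp. That was 0.310% of GATA2 peaks (95% Wilson interval 0.210 to 0.457) and 0.460% of GATA3 peaks (0.312 to 0.679). Random placements of the GATA3 peaks gave 7.26 ± 2.64 overlaps (SD over 1000 placements), so the observed count was 3.44 times chance (95% Poisson interval 2.229 to 5.08; two-sided permutation p = 0.002, the smallest these placements can give). The overlap covered 3778 bp, a Jaccard index of 0.00119. Of the 25 shared sites, 13 overlapped an annotated gene and 4 lay more than 500 kb from any, against 1.04% of all GATA2 peaks and 0.626% of all GATA3 peaks. Those 4 were a group on chromosome 1, between 124613288 and 124712902, and a site on chromosome 4, 50758662 to 50758912. Sites as close as that group may not be independent, though the Poisson interval takes them to be. The shared site in NRXN1 also overlapped the pseudogene MTCO1P42. Binding of both factors at the shared sites was not tested.

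The loci of the 2 factors were examined next. The GATA3 gene (chromosome 10, 8045333 to 8075198) had 1 GATA2 peak, at 8043786 to 8043994, whose midpoint lay 1.44 kb below the lower end of the gene. No GATA3 peak lay within 100 kb of it. The GATA2 gene (chromosome 3, 128479422 to 128493201) had no peak of either list within 100 kb.

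The position of peaks relative to genes differed between the lists. GATA3 peaks lay near gene ends more often than GATA2 peaks. Wherever they lay, the widest GATA3 peaks without a GATA2 peak were inside IGF2, which encodes a fetal growth factor, and ACTB, which encodes beta-actin. The IGF2 peak was 2190 bp wide (chromosome 11, 2130966 to 2133155) and also lay in the overlapping gene INS-IGF2. The ACTB peak was 1487 bp wide (chromosome 7, 5527182 to 5528668), and the next was 1027 bp wide in ANKRD30BL (chromosome 2, 132255145 to 132256171). The widest GATA2 peaks without a GATA3 peak were narrower: 760 bp on chromosome 9 (128032054 to 128032813), 28.8 kb from NAIF1, then 741 bp in CC2D2B on chromosome 10 (95926577 to 95927317) and 708 bp in LINC01234 on chromosome 12 (113750724 to 113751431). Within 1 kb of either end of an annotated gene lay 10.2% of GATA3 peaks (95% Wilson interval 9.44 to 11.1) and 6.25% of GATA2 peaks (5.74 to 6.80). The difference was 3.97 percentage points (odds ratio 1.71, Fisher's exact test, adjusted p = 7.43e-16 over 9 tests). Random placements put 6.62% of GATA3 peaks there, so the GATA3 share was 1.54 times chance (permutation p = 0.002, the smallest possible), while the GATA2 share was 0.962 times chance (p = 0.372). Intergenic peaks made up 34.4% of the GATA3 list and 39.4% of the GATA2 list. Among peaks of 400 bp or more, a class chosen after seeing the data, 56 of 242 GATA3 peaks lay near a gene end, or 23.1% (18.3 to 28.8), and 10 of 104 GATA2 peaks, or 9.62% (5.31 to 16.8).

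**Figure D1:**
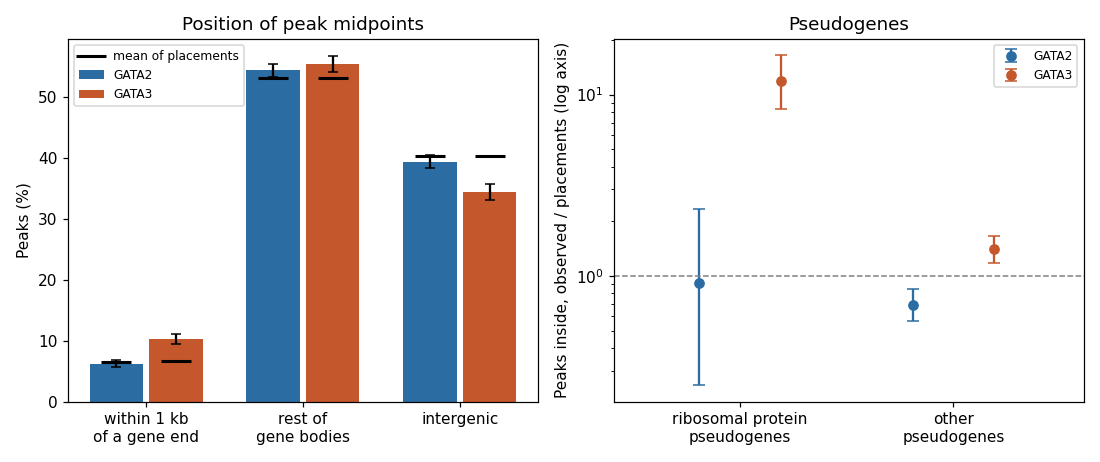
Left, percent of GATA2 (blue) and GATA3 (orange) peaks whose midpoint lay within 1 kb of a gene end, in the rest of gene bodies, or between genes; error bars are 95% Wilson intervals and black lines the mean of 1000 random placements. Right, peaks inside pseudogenes as a ratio to placements on a log axis, with 95% Poisson intervals: GATA3 peaks on ribosomal protein pseudogenes stood at 11.9 times chance and GATA2 peaks at 0.918.

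Whether the peaks lay at genes of the trophoblast lineages was asked with 14 gene lists fixed before the data were examined. GATA3 peaks occurred at genes of the syncytiotrophoblast and of extravillous trophoblast 2.32 and 2.01 times as often as at other genes of the same length. Syncytiotrophoblast genes with GATA3 peaks but no GATA2 peak included CGB3, a chorionic gonadotropin beta subunit gene, with 5 peaks in its body or within 25 kb, LEP, which encodes leptin, with 3, ERVW-1, which encodes the fusion protein syncytin-1, with 3, and LGALS16, a placental galectin gene, with 1. At LEP the nearest peak to a gene end lay at chromosome 7, 128241297 to 128241481, and at ERVW-1 at chromosome 7, 92477669 to 92477912, both inside the gene. CSH1, CSHL1, CGB7 and SDC1 had peaks of both lists, at separate sites. The nearest peak of each list was the same for CSH1 and CSHL1. Here and below, peaks of both lists at a gene need not be a shared site. Of the 58 syncytiotrophoblast genes, 25 had a GATA3 peak against 10.8 in length-matched random sets (2.32-fold, adjusted permutation p = 0.0028 over 28 tests), while 12 had a GATA2 peak against 12.1 (0.993-fold). The gonadotropin, placental lactogen and PSG genes lie in clusters of near-identical copies, so peaks inside them are uncertain. With clustered genes counted once, by the longest gene of each cluster, 16 of 45 had a GATA3 peak against 9.11. The call was lost (1.76-fold, adjusted permutation p = 0.187), but peaks at shorter genes of a cluster, such as LGALS16, did not count there.

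Of the 14 extravillous trophoblast genes with GATA3 peaks only, those named by the fixed rule were IGF2 with 4, FSTL3, an activin-binding protein gene, with 3, CDKN1C, an imprinted cell cycle inhibitor gene, with 2, and HTRA4, a placental serine protease gene, with 1. MMP14, ITGA5, TIMP3 and CSH1 had peaks of both lists. One of the CDKN1C peaks lay at chromosome 11, 2885075 to 2885740, and the HTRA4 peak at chromosome 8, 38974295 to 38974628, both inside the gene. Of the 48 genes, 19 had a GATA3 peak against 9.45 in random sets (2.01-fold, adjusted permutation p = 0.028), and 12 had a GATA2 peak against 11.4 (1.05-fold). The call was lost against genes matched on the number of neighbouring genes instead of on length (1.82-fold, 10.4 expected, adjusted permutation p = 0.101).

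Ribosomal protein genes, included as a list unrelated to the trophoblast, also passed the test for GATA3, and the sizes of the excess were not compared between lists. RPLP1, RPS2, RPL13A and RPL29 had a GATA3 peak in the gene body and no GATA2 peak within 25 kb, and RPS24, RPL15, RPS21 and RPL41 had peaks of both lists. Of the 78 genes, 25 had a GATA3 peak against 11.2 (2.232-fold, adjusted permutation p = 0.0028) and 13 a GATA2 peak against 12.3 (1.06-fold). The call was lost in the wider peaks (2.07-fold, adjusted permutation p = 0.189). It was also lost against genes matched on neighbours instead of on length (1.58-fold, 15.8 expected, adjusted permutation p = 0.151). Inside the gene body alone, 16 ribosomal protein genes had a GATA3 peak against 1.95 (8.21-fold), beside 15 syncytiotrophoblast genes against 4.56 (3.29-fold) and 14 extravillous genes against 4.13 (3.39-fold), each with adjusted permutation p = 0.00187. Counting only peaks outside every gene body but within 25 kb, none of the 3 lists passed: 6 syncytiotrophoblast genes against 2.48 (adjusted permutation p = 0.371), 4 extravillous genes against 2.21 (0.935) and 2 ribosomal protein genes against 3.33 (adjusted p = 1). Pseudogenes of ribosomal protein genes, of which 1989 are annotated, held 36 GATA3 peaks against 3.03 in random placements (11.9-fold, 95% Poisson interval 8.32 to 16.4) and 4 GATA2 peaks against 4.36 (0.918-fold, 0.250 to 2.35). Other pseudogenes held 132 GATA3 peaks against 94.0 (1.40-fold) and 95 GATA2 peaks against 137 (0.695-fold). The body, flank and pseudogene counts were chosen after seeing the data.

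**Figure D2:**
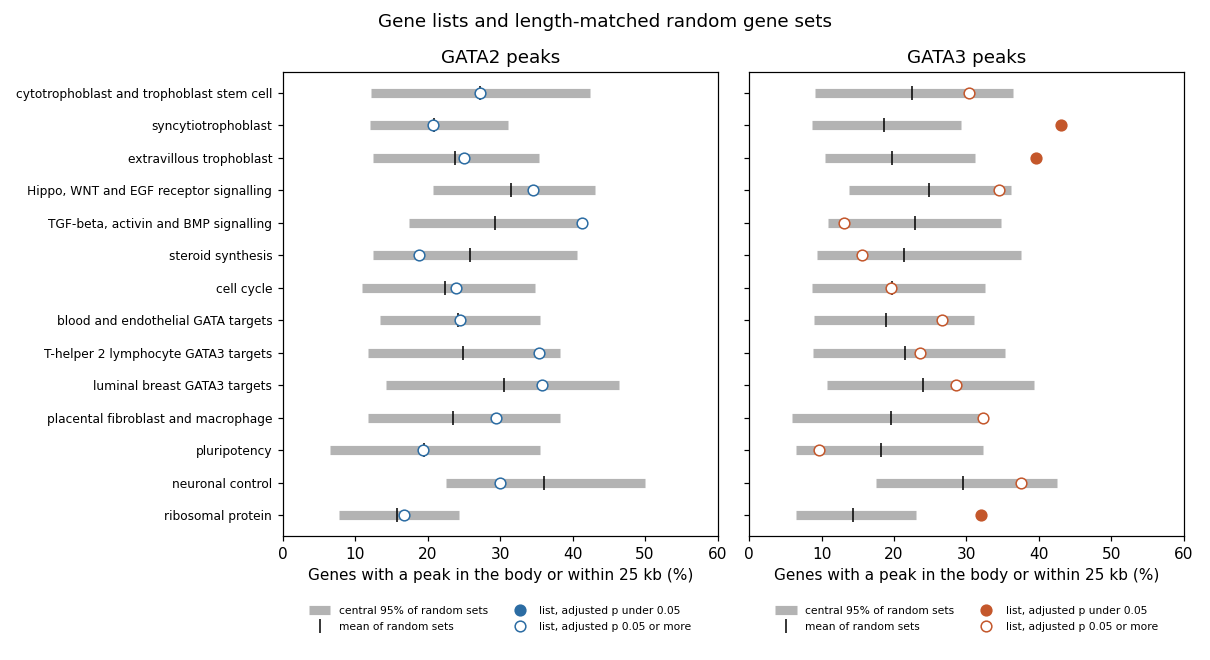
Percent of the genes of each fixed list with a GATA2 (left) or GATA3 (right) peak in the gene body or within 25 kb; filled circles mark an adjusted p under 0.05, grey bars the central 95% of 10000 length-matched random gene sets and ticks their mean. The filled GATA3 circles are syncytiotrophoblast (43.1%), extravillous trophoblast (39.6%) and ribosomal protein genes (32.1%), and every GATA2 circle is open.

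The other lists did not pass the test. In the cytotrophoblast and trophoblast stem cell list, KRT8 and KRT18, a keratin pair of simple epithelia whose annotated bodies overlap, had 6 and 2 GATA3 peaks, KRT7 had 1 GATA2 peak, and ITGA6 and ARID3A had peaks of both lists. Of its 33 genes, 10 had a GATA3 peak against 7.42 (adjusted permutation p = 0.855) and 9 a GATA2 peak against 8.97 (adjusted p = 1). Of 46 genes of TGF-beta, activin and BMP signalling, 19 had a GATA2 peak against 13.5 (1.41-fold, adjusted permutation p = 0.540) and 6 a GATA3 peak against 10.5 (0.569-fold, adjusted permutation p = 0.540). In the gene body alone, a count chosen after seeing the data, 15 had a GATA2 peak against 8.23 (1.82-fold, adjusted permutation p = 0.0714), and within 1 kb of a gene end 3 did against 0.488 (6.15-fold, Fisher's exact test, adjusted p = 0.0738). Its genes with GATA2 peaks only included TGFBR2, a TGF-beta receptor gene, with 2, and GREM1, a BMP antagonist gene, with 1, and SMAD4 had 1 peak of each list. Of 58 genes of Hippo, WNT and EGF receptor signalling, 20 had a GATA2 peak and 20 a GATA3 peak, against 18.3 and 14.4, with DUSP6 and AMOTL2 in the GATA2 list only and CTNNB1 and DVL1 in the GATA3 list only. Steroid synthesis genes numbered 6 of 32 for GATA2 against 8.25, HSD3B2 among them, and 5 for GATA3 against 6.84, with DHCR7 and DHCR24 among those. Cell cycle genes numbered 11 of 46 for GATA2 against 10.3 and 9 for GATA3 against 9.05. For the fibroblast and macrophage list, which stands for other placental cells, the numbers were 10 of 34 against 7.97 and 11 against 6.66, with COL1A2 and ACTA2 in both lists. GATA targets of other tissues did not pass either: 11 of 45 blood and endothelial genes for GATA2 against 10.9 and 12 for GATA3 against 8.51, 12 of 34 T-helper 2 genes against 8.44 and 8 against 7.31, and 10 of 28 luminal breast genes against 8.55 and 8 against 6.73. Within 1 kb of either gene end, the luminal breast list passed for GATA3, with 3 genes against 0.368 (8.15-fold, Fisher's exact test, adjusted p = 0.0415). They were the keratin genes KRT8, KRT18 and KRT19. KRT8 and KRT18 share a peak within that distance and are also in the cytotrophoblast list, so the test did not count separate loci. Pluripotency genes numbered 6 of 31 against 6.02 and 3 against 5.62, and neuronal genes 12 of 40 against 14.4 and 15 against 11.8. GATA2 thus had 0 of 14 lists past the threshold by permutation, while GATA3 had 3.

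Whether a list leaned to one factor was tested on genes with a peak of 1 list only. The other genes were not matched on length or neighbours, so the test cannot separate the list from the size and density of its genes. Syncytiotrophoblast and ribosomal protein genes passed this test, toward GATA3, but neither did once clustered genes were counted once. Among syncytiotrophoblast genes 20 had only GATA3 peaks and 7 only GATA2 peaks, a GATA3 share of 74.1% against 43.4% in other genes (Fisher's exact test, adjusted p = 0.0219 over 14 tests). Among ribosomal protein genes the numbers were 21 and 9, or 70.0% (exact test, adjusted p = 0.0337). Genes of TGF-beta, activin and BMP signalling had 2 with GATA3 peaks only and 15 with GATA2 peaks only, or 11.8%, which did not pass the exact test (adjusted p = 0.0549). Extravillous genes had 14 and 7, or 66.7%, and did not pass either (exact test, adjusted p = 0.158). With clustered genes counted once, a count chosen after seeing the data, the GATA3 share was 68.4% in syncytiotrophoblast genes, 13 against 6 (exact test, adjusted p = 0.158) and 69.0% in ribosomal protein genes, 20 against 9 (adjusted p = 0.0823), and within 100 kb of either gene end neither passed (adjusted p = 0.351 and 0.527). With the GATA2 list reduced to the GATA3 size by width, TGF-beta genes passed (exact test, 2 and 11, adjusted p = 0.0321) and ribosomal protein genes did not (24 and 7, adjusted p = 0.0526). Over all 20037 protein-coding genes, 5235 had a GATA2 peak, 4364 a GATA3 peak and 1436 both. From the 2 shares alone, without regard to gene length, 1140 genes with both were expected.

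Genes with the most peaks within 100 kb of an end differed by list. For GATA3 these were CGB3 with 9, KRT8 with 7, TIMP3, CLASP1 and DET1 with 6 each, and LRRC75A, BSG, TUBA1B, NOL4L and CHD9 with 5 each. For GATA2 they were EIF3J, SPRY3, CLBA1, FYCO1, DAB1 and DYNC1H1 with 6 each, and PMFBP1, CFAP97D2, AKT2 and MTMR3 with 5 each. Genes near one already taken were left out and ties went to the nearest peak, so unnamed genes such as KRT18 can have as many. The counts were not tested.

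Among chromosomes 1 to 22 and X, both lists were densest on chromosome 19, the most gene-dense of these. It held 3.46 GATA2 peaks per Mb (95% Poisson interval 3.00 to 3.97), 1.30 times the GATA2 density over chromosomes 1 to 22 and X, and 3.17 GATA3 peaks per Mb (2.73 to 3.66), 1.78 times the GATA3 density. Of the same chromosomes, chromosome 13 was sparsest in both lists, with 1.97 GATA2 peaks per Mb (1.72 to 2.24) and 1.30 GATA3 peaks per Mb (1.10 to 1.53). Full chromosome lengths were used, so these densities and their order were not corrected for assembly gaps.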

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

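The gene body, flank and pseudogene counts, the list difference with clustered genes counted once, the tests on ribosomal protein pseudogenes, and the flank counts of clustered genes and of other lists were chosen only after the result was seen.

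Of the comparisons, peaks outside the chromosomes analysed entered only the alternative overlap over all contigs. The GATA3 list held 12 peaks on the mitochondrial genome (95% Poisson interval 6.20 to 20.96) and the GATA2 list held 0 (0 to 3.69). Unplaced or unlocalised contigs held 40 GATA2 and 14 GATA3 peaks. Between the antibodies, the share within 1 kb of a gene end differed by 3.97 percentage points. Among genes with a peak of 1 list only, the GATA3 share differed from that of other genes for syncytiotrophoblast genes (74.1%) and for ribosomal protein genes (70.0%), though with clustered genes counted once neither passed (adjusted p = 0.158 and 0.0823, Fisher's exact test).

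GATA3 peaks lay inside genes taken to have abundant transcripts, ribosomal protein genes among them, and fragments derived from RNA are a candidate source. No transcript levels were used here, so abundance in these cells was assumed. Of 74 other genes assumed to have abundant transcripts, listed before their peaks were seen, 26 had a GATA3 peak in the body. Length-matched sets gave 4.57 (5.69-fold), and EEF2, ENO1, FLNA and TPT1 were among the 26. Of the same 74 genes, 3 had a GATA2 peak against 5.17. Ribosomal protein pseudogenes held 11.9 times the GATA3 peaks of random placements, against 0.918 times for the GATA2 list. That comparison cannot decide on ambiguous alignment of reads from the parent genes. Of 78 ribosomal protein genes, 16 held a GATA3 peak in the body but only 1 a GATA2 peak, so the GATA2 list had little to misplace. Cutting at accessible ends of active genes stays open. Of the 37 GATA3 peaks in abundant-transcript and ribosomal protein genes over 4 kb, 29.7% lay within 1 kb of an end (95% interval 17.5 to 45.8). That was above the 14.4% of gene body there but not most of the peaks. Per the labels the stop buffer held RNase A, binding of GATA3 at these genes was not tested, and no IgG list was used that could separate these explanations.

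Syncytiotrophoblast and extravillous genes also had GATA3 peaks in the gene body above random sets, and RNA of these genes may contribute to it. The flank test, chosen after the list excess was seen but with its bound written before the flank counts were, took an excess outside every gene body as evidence against RNA, and 10 of 104 genes had such a GATA3 peak against 4.65 (2.15-fold, random sets 1 to 9), or 8 of 89 against 4.03 with clustered genes counted once (1.99-fold, random sets 1 to 8). The 11 lists outside the trophoblast exceeded random sets there as well, with 36 of 436 genes against 19.4 (1.85-fold, random sets 11 to 28), so that excess is not particular to these genes and RNA stays open. Taken singly those lists ranged from 0.487 (TGF-beta signalling) to 3.52 (neuronal), and none of them, nor either trophoblast list, passed after adjustment. Clusters counted several times did not account for all of the joint excess, since 34 of 89 genes had a GATA3 peak in the body or within 25 kb (1.89-fold, random sets 11 to 25), and binding of GATA3 stays open and untested.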

How the results depend on the processing

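Tests with local placements, without peaks over 500 kb from a gene, in the gene body only, outside every gene body, within 25 kb of either gene end, without peaks on pseudogenes, and the list difference with clustered genes counted once were chosen only after the result was seen. Leaving aside counts of lists, 67 of 77 values under alternatives kept their direction and call or stayed within counting error, 9 lost a call and 1 changed direction. Those kept include the cytotrophoblast list for GATA3 and the TGF-beta list for GATA2, which passed in no setting. All 9 losses and the change of direction were in the 3 gene lists that passed for GATA3. The overlap stayed above chance in every alternative with its own placements, from 1.67-fold (peaks within 1000 bp) to 5.97-fold (wider peaks), as did the GATA3 share near gene ends. Over all contigs the overlap count stayed at 25, but no placements were run there, so its call could not be lost. By distance to either gene end, GATA3 ratios were taken against all other genes, not against length-matched sets. On that baseline the ratios within 25 kb were 2.36 for syncytiotrophoblast, 2.25 for extravillous and 1.82 for ribosomal protein genes (3 lists passed). Within 10 kb they were 3.37, 3.10 and 2.80 (3 lists), and within 1 kb 13.5, 14.6 and 8.96 (4 lists, luminal breast added). In genes as short as CGB3 or CSH1 any peak in the body lies within 1 kb of an end. Within 100 kb of a gene end, GATA3 had 0 lists past the threshold against 3, with ratios of 1.31 for syncytiotrophoblast, 1.40 for extravillous and 1.40 for ribosomal protein genes, and 0 lists differed between the factors against 2, as also (0) in the list difference with clustered genes counted once. Matching on neighbouring genes, in place of length, left 1 GATA3 list, syncytiotrophoblast, with 1.82 for extravillous and 1.58 for ribosomal protein genes. Gene density and the dropped length match cannot be told apart in these losses. Outside every gene body 0 GATA3 lists passed, with 2.42 for syncytiotrophoblast and 1.81 for extravillous genes, and ribosomal protein genes turned to 0.600. Counting clusters once gave 1.76 for syncytiotrophoblast genes, and the wider peaks 2.07 for ribosomal protein genes, with 2 GATA3 lists each. Fewer genes entered the former and fewer peaks the latter, and both of these ratios were also below those of the main test. The cause was not tested for any of the losses. GATA2 had 0 lists in every alternative run. The planned motif alternatives and the promoter from 2000 bp upstream were not run, for want of sequence and strand. No paired analysis was possible because each antibody had 1 pooled sample. Unknown depth and the missing scores limit every statement on peaks not found.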

Other observations

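The test without peaks far from genes was chosen only after the result was seen.

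Further wide GATA3 peaks lay in genes outside the trophoblast lists. CALR, an endoplasmic reticulum chaperone gene, held peaks of 830 and 775 bp, HSPA5, another, 1 of 518 bp, GAPDH 1 of 691 bp and PKM 1 of 623 bp. PABPC1, a poly(A)-binding protein gene, held 1 of 560 bp. Pseudogenes were among the widest as well, with 978 bp at RPLP0P6, 914 bp at RPL4P4, 787 bp at ANXA2P2 and 740 bp at EEF1A1P5. These genes were chosen after their values were seen.

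The near absence of overlap between GATA2 and GATA3 lists may mean that most intervals are background of the call, or that the antibodies mark different sites. Among wider peaks the overlap was 5.97 times chance (13 sites, 95% Poisson interval 3.18 to 10.2) against 3.44 in the full lists, which lies between what the 2 outcomes set beforehand required, so background stays open. Shared sites far from genes do not make up the excess, since without peaks over 500 kb from any gene it was 3.05 times chance, but repeats in or near genes were not tested, as no repeat annotation was used. Different sites cannot be told apart from background here, because there is only 1 list per antibody (lists per antibody in the files, 1).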
